A study of Mus musculus with 14 samples.

How the data were processed

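Total RNA of mouse embryonic fibroblasts was sequenced in 14 libraries, 2 in each of 7 groups, with groups and replicate numbers taken from the sample labels. Per the labels' protocols, starved cells were kept in medium without amino acids or without glucose and with dialyzed serum, and cells were trypsinised and frozen before sequencing. The deposited table holds whole-number counts of reads per transcript, not normalised as far as their values show. Per the submitters' processing notes, the genome build GRCm39 and the tools STAR, an aligner, and bedtools were used, with versions, annotation release and counting rules not given in the sources used here. Whether counting used strand is not stated either, so that reads of antisense and overlapping genes cannot be told apart.

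The table had 67457 lines, one per transcript, of which 58 named no gene and held 0% of the reads. Of 40800 genes, 13432 (32.9%) had several transcripts whose counts nearly repeat each other, so that a sum would count reads more than once. Each gene was represented by its transcript with the most reads over all libraries. This left 35270767 to 55349659 reads per library. Genes with near-identical copies or overlapping neighbours are uncertain where the authors' counting could have split or repeated their reads. The reference at hand was of the build GRCm38, so no coordinates are given, and it served only for GC content, transcript length, neighbours and overlaps. GC content was known for 17346 tested genes (98%), and 16988 (96%) were found in the annotation. Of the tested genes, 7269 (41.1%) overlap another annotated gene.

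Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were filtered with filterByExpr on the groups, which left 17696, libraries were scaled with TMM, and a quasi-likelihood model (glmQLFit, robust) of 7 group means was fitted to all 14 libraries, with 7 residual degrees of freedom before moderation. The spread was pooled over groups. The biological coefficient of variation was 5.78% and the median prior degrees of freedom 20.9. The 12 two-sided comparisons were each starvation time against the control, amino acid against glucose starvation at each time, 12 h against 3 h of each starvation, and the difference of these changes. P-values were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05, and calls were also counted at an absolute log2 fold change of at least 1. CPM are counts scaled to a common library total with TMM factors. Counts were simulated for 12 h of amino acid starvation against the control (16649 genes). Of genes changed by a log2 of 0.5, 1 and 2, 61.2% of 67, 95.5% of 67 and 100% of 66 were recovered. Of 182 calls, 11 (6%) were false, and an unchanged comparison gave 0. Few genes changed there, unlike here, so scaling was untested.

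In advance, 34 gene lists with 706 entries were fixed, and all 706 were found in the table. They held targets of ATF4, FOXO, NRF2, p53, YAP and of MondoA and ChREBP, aminoacyl-tRNA synthetases, amino acid transporters, and serine and one-carbon synthesis. Others held ER chaperones and ER-associated degradation, autophagy, lysosome and TFEB targets, cholesterol and fatty acid synthesis, glycolysis, hypoxia-inducible genes, nuclear (OXPHOS) and mitochondrial genes of the respiratory chain. The rest held ribosomal proteins, ribosome biogenesis, DNA replication, mitosis, immediate early, heat shock, matrix, inflammatory and interferon-stimulated genes, and markers of other cell types (macrophage, endothelial, skeletal muscle, adipocyte, neural, epithelial, erythroid). Lists with at least 3 measured members were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. They were tested again with an estimated correlation, with fry, which asks whether a list's genes move one way without comparing them with other genes, and with the replicate number as a block. Of 224 calls by camera over the 12 comparisons, 145 held with an estimated correlation, and each call named in the text that was lost has that p beside it.

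The rule for named genes, also fixed before, takes a panel of 24 genes. It adds the 6 highest and 6 lowest log2 fold changes per comparison among called genes with a mean log2 CPM of at least 3, libraries that do not overlap between groups and no provisional symbol (3 and 3 for changes over time and their difference). It further adds up to 4 called members with the smallest p per list. Some genes that the rule takes are not reported here. Alternatives fixed before were RLE factors or library totals for scaling, DESeq2 1.42.0, no filter (at least 1 read) or a stricter filter (CPM of 1 in 4 libraries), only the groups compared, the replicate number as a block, and leaving out each library. Chosen after seeing the data were the longest transcript per gene, a correction for GC content and length, and leaving out genes that overlap another.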

Results

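Mouse embryonic fibroblasts, connective tissue cells cultured from mouse embryos, were deprived of amino acids or of glucose, and their total RNA was sequenced. The series concerns the response of cells to nutrient loss and its autophagy processes, the breakdown of cell contents in lysosomes. The 14 libraries fell into 7 groups of 2: untreated control cells at 0 h, and cells after 3, 6 and 12 h of either starvation. Starved cells received medium with dialyzed serum and were frozen in dialyzed serum, whereas control cells had no change of medium and were frozen in ordinary serum. Each comparison with the control therefore includes that handling, which both starvations at the same time share. The labels do not say that the 2 libraries of a group came from separate cultures, so that p-values measure only the spread between these samples, which may be technical.

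With 1 transcript standing for each gene, the control libraries held 43599405 and 43305344 reads. After 3, 6 and 12 h of amino acid starvation they held 42556095 and 45434192, 42352167 and 55349659, and 42374126 and 46090776 reads. Those of glucose starvation held 35270767 and 37089790, 35829306 and 42380978, and 54990631 and 38448194 reads at the same times. Transcripts of the mitochondrial genome made up 5.41% ± 0.68 (SD, n = 2) of control reads, 4.0% ± 0.065, 4.92% ± 0.081 and 4.65% ± 0.41 along amino acid starvation, and 6.54% ± 0.054, 6.32% ± 0.14 and 5.17% ± 0.037 along glucose starvation. Levels below are CPM, counts scaled to a common library total, given as mean ± SD of n = 2 libraries, and log2 fold changes carry their standard error (SE). Genes said to rise, fall or differ passed edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05, over 17696 genes tested. The largest changes named below are taken among those that meet the rule for named genes, with a mean log2 CPM of at least 3, and genes of lower counts can exceed them. Gene lists were tested with camera, and the numbers of their members that rose and fell are counted over all genes tested, followed by the numbers adjusted over the list alone wherever these differ. Medians of lists are of log2 fold changes. The median of a list that passed is followed by its value with library totals or after correction for GC content and length where either moved it by over 1.5 times. Several genes named below, among them Txnip, Sqstm1, Ccnd1, Gabarapl1, Slc6a9, Hmgcs1, Gas1, Gadd45a, Angptl6, Mast1, Tagln, Serpinb2, Cln3 and Apobr, overlap another annotated gene, and the source of part of their reads is uncertain.

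The first principal component of log2 CPM, with 37.3% of the variance, set the libraries after 12 h of amino acid starvation (scores of 94.8 and 95.1) apart from those after 3 h of glucose starvation (-65.7 and -67.3). The second component (26.7%) ran from 3 h of amino acid starvation (81.7 and 81.5) to 12 h of glucose starvation (-71.1 and -74.2), and the third (11.3%) placed the control (-63.1 and -62.5) below every starved group. Across genes, the log2 CPM of the 2 libraries of a group correlated with r of 0.988 to 0.992, and their counts differed beyond sampling noise in every group (chi-square per degree of freedom of 3.46 to 14.6 over genes, which are not independent replicates).

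**Figure D1:**
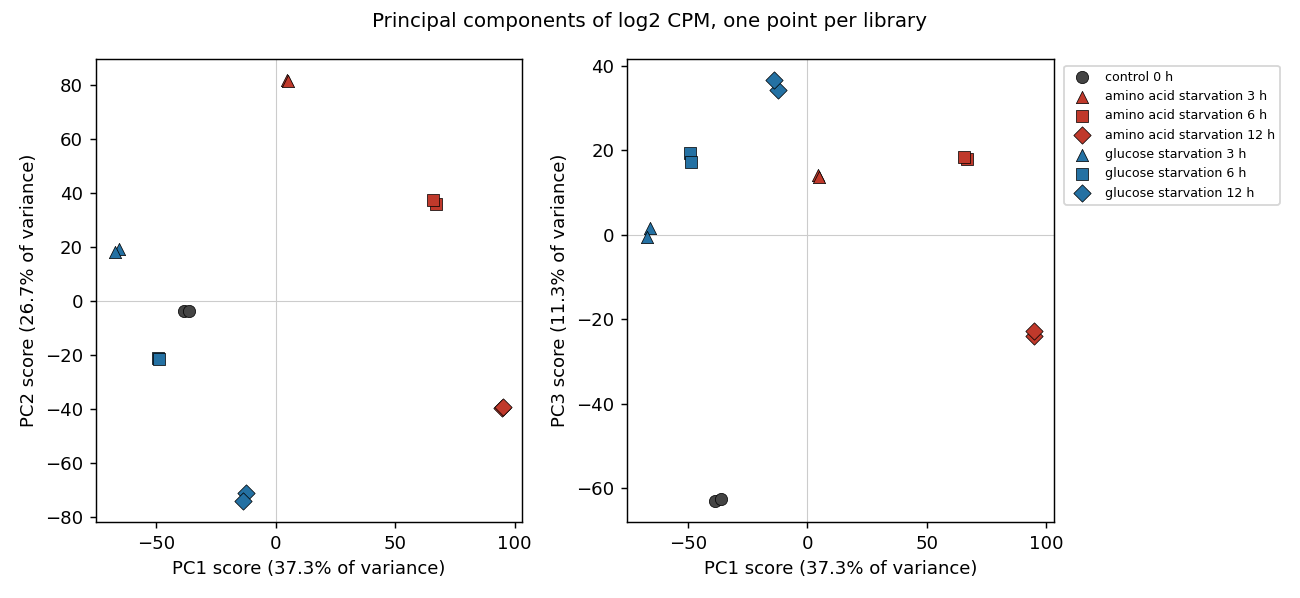
Scores of the 14 libraries on the first 3 principal components of log2 CPM over 17696 genes, with 1 point per library, the color giving the treatment and the shape the time. The control lies at -63.1 and -62.5 on the third component, away from all starved groups.

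After 3 h of amino acid starvation, genes of the integrated stress response, immediate early genes and inflammatory genes were higher than in the control, and genes of cholesterol synthesis were lower. Trib3, a pseudokinase gene induced by the transcription factor ATF4, rose from 6.88 ± 1.2 to 227 ± 5.2 CPM (log2 fold change 5.04, SE 0.079, edgeR adjusted p = 2.79e-28). Asns, encoding asparagine synthetase, rose from 98.3 ± 1.6 to 451 ± 11 CPM, and Atf4 itself from 309 ± 7.2 to 1154 ± 28 CPM (log2 fold change 1.90, SE 0.054, edgeR adjusted p = 2.51e-22). Among the targets of ATF4, 34 of 34 rose and 0 fell (median 2.53, camera adjusted p = 5.34e-110). Chac1, whose product degrades glutathione, rose from 12.1 ± 0.059 to 243 ± 4.1 CPM, and the mTORC1 inhibitors Sesn2 and Ddit4 rose from 16.9 ± 0.80 to 140.1 ± 0.54 CPM and from 18.9 ± 1.6 to 189 ± 3.7 CPM. Of the aminoacyl-tRNA synthetases, 14 of 20 rose and 3 fell (median 0.84, camera adjusted p = 1.23e-11). Of the amino acid transporters, 15 of 20 rose and 3 fell (median 1.57, camera adjusted p = 2.8e-21). The glycine carrier Slc6a9 was at 218 ± 2.3 against 18.1 ± 0.44 CPM, and the cationic amino acid carrier Slc7a1 at 1138 ± 52 against 110.0 ± 0.76 CPM. In serine and one-carbon synthesis, 9 of 11 rose and 1 fell (median 1.21, camera adjusted p = 2.94e-13).

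The largest increases at 3 h of amino acid starvation, beside Trib3, were those of Fosb (62.4 ± 0.95 against 0.764 ± 0.34 CPM), a subunit of the AP-1 transcription factor and Serpinb2 (19 ± 1.8 against 0.262 ± 0.12 CPM), a protease inhibitor. The others were Soat2 (4.92 ± 1.2 against 0.0983 ± 0.015 CPM), a cholesterol esterifying enzyme, Areg (45.9 ± 0.72 against 1.49 ± 0.22 CPM), a growth factor, and Atf3 (241 ± 7.9 against 8.15 ± 0.44 CPM), a stress transcription factor. Immediate early genes, which respond rapidly to serum and stress, rose as a group: 24 of 24 rose and 0 fell (median 2.94, camera adjusted p = 7.98e-77). Egr1 reached 1352 ± 13 CPM against 82.3 ± 0.35, and Myc 716 ± 15 against 105 ± 9.4 CPM. In the inflammatory list, 15 of 21 rose and 0 fell (16 and 0 adjusted over the list alone, median 1.29, camera adjusted p = 8.24e-16), with Ptgs2, which encodes cyclooxygenase 2, at 713 ± 22 against 30.1 ± 1.4 CPM. The hypoxia-inducible list also rose, as 6 of 14 rose and 4 fell (median 0.22, or 0.04 with library totals, camera adjusted p = 1.38e-08). Vegfa was at 639.6 ± 0.94 against 34.9 ± 0.30 CPM and Ndrg1 at 455 ± 10.3 against 23.2 ± 0.55 CPM. Targets of FOXO factors rose as a group (11 higher, 3 lower of 16, median 1.02, camera adjusted p = 1.11e-10). So did targets of p53 (11 higher, 7 lower of 21, 11 and 8 adjusted over the list alone, median 0.53, camera adjusted p = 9.41e-07) and of YAP (11 higher, 1 lower of 15, median 0.82, camera adjusted p = 8.31e-07). Gadd45a, a p53 target, rose from 5.81 ± 0.20 to 159.9 ± 4.6 CPM, and Cdkn1a, an inhibitor of the cell cycle, from 24.2 ± 0.52 to 284 ± 5.2 CPM.

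Sterol genes fell at 3 h of amino acid starvation. In the cholesterol list, 1 of 25 rose and 23 fell (median -0.81, camera adjusted p = 2.38e-11). The synthesis genes Hmgcs1 and Dhcr7 fell from 112 ± 4.2 to 41.4 ± 0.92 CPM and from 33.8 ± 2.7 to 7.03 ± 0.20 CPM. The largest falls were those of Chst12 (1.43 ± 0.086 against 38.9 ± 0.11 CPM), a sulfotransferase and Zfp41 (1.54 ± 0.18 against 17.8 ± 0.28 CPM). The others were Sapcd2 (2.09 ± 0.14 against 19.4 ± 2.3 CPM), Cyp1b1 (8.66 ± 0.64 against 67.4 ± 2.3 CPM), a cytochrome P450, Gas1 (3.79 ± 0.35 against 27.2 ± 2.4 CPM) and Tmem104 (1.94 ± 0.47 against 13.4 ± 0.33 CPM). In the autophagy list, 25 of 45 rose and 11 fell (median 0.18, or 0.008 with library totals, camera adjusted p = 0.00103). The cargo receptor gene Sqstm1 rose from 247 ± 12 to 1368 ± 2.2 CPM (log2 fold change 2.47, SE 0.055, edgeR adjusted p = 8.25e-25), and Map1lc3b, Gabarapl1 and Ulk1 had log2 fold changes of 0.82, SE 0.060, 1.51, SE 0.072 and 0.67, SE 0.073. Genes of DNA replication rose (21 higher, 2 lower of 26, 22 and 2 adjusted over the list alone, median 0.47, or 0.29 with library totals, camera adjusted p = 5.67e-05) and ribosome biogenesis genes rose (22 higher, 4 lower of 30, median 0.38, or 0.20 with library totals, camera adjusted p = 0.000144). Ccnd1, encoding cyclin D1, fell from 249.9 ± 5.2 to 95.9 ± 4.0 CPM. In total 10618 genes passed, 4936 higher and 5682 lower. Among them, 3430 changed at least 2-fold (1750 higher, 1680 lower). With library totals as the only scaling, 34.2% of the calls were higher instead of 46.5%, and 37.2% instead of 51.0% of those of at least 2-fold. Without genes that overlap another, 10438 genes were tested and 6239 passed, and the calls of the other comparisons fell as well.

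After 6 h of amino acid starvation the stress genes were higher than in the control, and sterol, fatty acid and heat shock genes were lower. Trib3 stood at 347 ± 2.8 against 6.88 ± 1.2 CPM, Asns at 790.3 ± 6.2 against 98.3 ± 1.6 CPM (log2 fold change 3.01, SE 0.056, edgeR adjusted p = 9.53e-27) and Slc7a11, the cystine carrier, at 234 ± 1.0 against 7.57 ± 1.6 CPM. Of the ATF4 targets, 34 of 34 rose and 0 fell (median 2.80, camera adjusted p = 5.79e-106). Synthetases (15 higher, 4 lower of 20, median 1.22, camera adjusted p = 3.93e-16) and transporters (14 higher, 5 lower of 20, median 1.94, camera adjusted p = 1.65e-20) were also mostly higher. One-carbon genes were mostly higher as well (9 higher, 1 lower of 11, median 1.62, camera adjusted p = 7.47e-19), with Aldh1l2, a mitochondrial folate enzyme, at 544 ± 16 against 76.8 ± 0.69 CPM. The largest increases were those of Soat2 (18.8 ± 0.45 against 0.0983 ± 0.015 CPM), Serpinb2 (20.4 ± 0.29 against 0.262 ± 0.12 CPM), Trib3, Slc7a11, Acot2 (80.6 ± 3.1 against 2.91 ± 0.47 CPM), a mitochondrial acyl-CoA thioesterase, and Cln3 (38.8 ± 1.2 against 1.65 ± 0.17 CPM), a lysosomal membrane protein. In the autophagy list, 27 of 45 rose and 10 fell (27 and 11 adjusted over the list alone, median 0.53, camera adjusted p = 1.82e-05). Sqstm1 was at 1243 ± 12 against 247 ± 12 CPM, Map1lc3b at 226 ± 5.4 against 107 ± 0.58 CPM, Gabarapl1 at 106 ± 5.8 against 33.1 ± 4.0 CPM and the conjugation gene Atg12 at 65.7 ± 1.8 against 22.2 ± 2.2 CPM. In the lysosome list, 25 of 47 rose and 14 fell (median 0.19, or 0.11 with library totals and 0.32 after GC and length correction, camera adjusted p = 0.0166, adjusted p = 0.258 with estimated correlation).

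The cholesterol list was lower at 6 h of amino acid starvation, and 1 of 25 rose and 24 fell (median -1.37, camera adjusted p = 9.39e-22). Hmgcs1 fell from 112 ± 4.2 to 31.8 ± 0.69 CPM. In fatty acid synthesis, 0 of 13 rose and 10 fell (median -0.72, camera adjusted p = 4.04e-08). The desaturase Scd2 was at 123 ± 0.70 against 1069 ± 37 CPM and the elongase Elovl6 at 7.48 ± 0.42 against 75 ± 3.9 CPM. Among heat shock proteins, 1 of 16 rose and 12 fell (median -0.76, camera adjusted p = 4.04e-08), and Hspa8, a constitutive Hsp70, fell from 3853 ± 72 to 1158 ± 5.9 CPM. Matrix genes (5 higher, 21 lower of 28, median -0.52, camera adjusted p = 1.55e-05, adjusted p = 0.168 with estimated correlation) included Col1a2 at 199 ± 3.7 against 1155 ± 52 CPM. The largest falls also included Cyp1b1 (3.1 ± 0.18 against 67.4 ± 2.3 CPM), Chst12 (2.89 ± 0.45 against 38.9 ± 0.11 CPM) and the actin-binding calponin Cnn2 (27.1 ± 0.23 against 346 ± 8.4 CPM). Interferon-stimulated genes fell (0 higher, 13 lower of 19, median -1.17, camera adjusted p = 0.000731). Nuclear genes of the respiratory chain were mostly lower (1 higher, 26 lower of 30, 1 and 27 adjusted over the list alone, median -0.44, or -0.27 after GC and length correction, camera adjusted p = 9.52e-05, adjusted p = 0.346 with estimated correlation). DNA replication genes rose (22 higher, 4 lower of 26, median 0.61, camera adjusted p = 1.5e-06). Ccnd1 fell from 249.9 ± 5.2 to 42.6 ± 3.0 CPM. The test passed 11606 genes, 5717 higher and 5889 lower. Of these, 4501 changed at least 2-fold (2217 higher, 2284 lower).

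After 12 h of amino acid starvation, matrix and heat shock genes were below the control. ATF4 targets and autophagy genes were above it. Col1a2, a chain of type I collagen, fell from 1155 ± 52 to 53.4 ± 0.59 CPM, Col1a1 from 2352 ± 189 to 312 ± 15 CPM and Sparc from 1274 ± 2.0 to 289 ± 1.1 CPM. Of the matrix list, 2 of 28 rose and 23 fell (2 and 24 adjusted over the list alone, median -1.72, camera adjusted p = 2.92e-32). Cnn2 fell from 346 ± 8.4 to 15.2 ± 0.61 CPM and Ccnd1 from 249.9 ± 5.2 to 10.5 ± 0.33 CPM (log2 fold change -4.57, SE 0.070, edgeR adjusted p = 1.56e-28). The largest falls were completed by Ly6a (0.218 ± 0.095 against 25.9 ± 0.85 CPM), Cxcl1 (0.87 ± 0.32 against 26.3 ± 3.0 CPM), a chemokine, Cyp1b1 (2.6 ± 0.28 against 67.4 ± 2.3 CPM) and Sorbs2 (0.298 ± 0.15 against 6.92 ± 0.13 CPM). Of the heat shock list, 1 of 16 rose and 14 fell (median -1.27, camera adjusted p = 5.07e-15). Hspa8 was at 478 ± 3.5 against 3853 ± 72 CPM and Hsp90ab1 at 1057 ± 16 against 4350.5 ± 159 CPM. Of the chaperones and degradation factors of the endoplasmic reticulum (ER), 6 of 24 rose and 17 fell (median -0.42, camera adjusted p = 0.00187, adjusted p = 0.19 with estimated correlation). Targets of YAP fell (1 higher, 13 lower of 15, median -1.16, camera adjusted p = 7.74e-10). The target Ccn2 was at 20.9 ± 0.68 against 194 ± 14 CPM. Inflammatory genes (3 higher, 14 lower of 21, median -1.25, camera adjusted p = 9.14e-06) and NRF2 targets (3 higher, 18 lower of 22, median -0.88, camera adjusted p = 0.000699) fell too.

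Of the ATF4 targets, 34 of 34 rose and 0 fell (median 2.48, camera adjusted p = 1.88e-65) at 12 h, and Trib3 stood at 348 ± 5.0 against 6.88 ± 1.2 CPM. The largest increases were those of Soat2 (27.9 ± 1.7 against 0.0983 ± 0.015 CPM), Angptl6 (31.1 ± 1.2 against 0.481 ± 0.15 CPM), a secreted angiopoietin-like protein, Trib3, Acot2 (87.6 ± 2.6 against 2.91 ± 0.47 CPM), Apobr (213 ± 5.4 against 7.79 ± 0.22 CPM), a lipoprotein receptor, and Cln3 (38.1 ± 4.9 against 1.65 ± 0.17 CPM). In the autophagy list, 36 of 45 rose and 2 fell (median 0.54, camera adjusted p = 2.69e-07). Ulk1, the kinase that starts autophagosome formation, rose from 49 ± 0.39 to 96.1 ± 8.0 CPM (log2 fold change 0.97, SE 0.073, edgeR adjusted p = 1.04e-12), and the receptor gene Nbr1 rose from 81.7 ± 3.8 to 211 ± 3.9 CPM. Lysosome and TFEB targets were also more often higher, as 30 of 47 rose and 8 fell (median 0.39, camera adjusted p = 4.63e-05, adjusted p = 0.0629 with estimated correlation). The calcium channel Mcoln1 was at 111 ± 0.42 against 36.8 ± 1.4 CPM. Cholesterol genes (0 higher, 24 lower of 25, median -1.18, camera adjusted p = 9.58e-14) and fatty acid genes (2 higher, 10 lower of 13, median -0.78, camera adjusted p = 6.54e-07) fell. Glycolysis genes were mostly lower (1 higher, 18 lower of 23, 1 and 19 adjusted over the list alone, median -0.63, camera adjusted p = 4.43e-05, adjusted p = 0.0901 with estimated correlation). DNA replication genes rose (22 higher, 3 lower of 26, median 0.70, camera adjusted p = 8.32e-08), including Cdc6 at 242 ± 6.3 against 77.3 ± 5.3 CPM. Txnip, whose transcription follows glucose metabolites, rose from 8.94 ± 0.93 to 48.7 ± 2.3 CPM. In total 11841 genes passed, 6171 higher and 5670 lower. Among them, 4817 changed at least 2-fold (2310 higher, 2507 lower). With library totals alone, 58.3% of those of at least 2-fold were higher instead of 48.0%.

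After 3 h of glucose starvation, Txnip was nearly lost, and stress, inflammatory, YAP and immediate early genes were higher than in the control. Txnip fell from 8.94 ± 0.93 to 0.358 ± 0.26 CPM (log2 fold change -4.65, SE 0.24, edgeR adjusted p = 9.24e-16). Trib3 rose from 6.88 ± 1.2 to 85 ± 3.8 CPM and Atf4 from 309 ± 7.2 to 837 ± 32 CPM (log2 fold change 1.44, SE 0.053, edgeR adjusted p = 4.44e-19). Hspa5, which encodes the endoplasmic reticulum chaperone BiP, rose from 1419 ± 8.2 to 3394 ± 45 CPM (log2 fold change 1.26, SE 0.053, edgeR adjusted p = 7.25e-18). Of the ATF4 targets, 32 of 34 rose and 0 fell (33 and 0 adjusted over the list alone, median 1.53, camera adjusted p = 1.13e-92). Of the ER list, 21 of 24 rose and 0 fell (22 and 0 adjusted over the list alone, median 0.40, or 0.23 with library totals, camera adjusted p = 9.55e-11). Herpud1 was at 288 ± 16 against 75.1 ± 1.8 CPM. The largest increases were those of Serpinb2 (13.3 ± 0.66 against 0.262 ± 0.12 CPM) and the clotting initiator F3 (260.4 ± 0.18 against 15.8 ± 1.0 CPM). The others were Ptgs2 (486 ± 39 against 30.1 ± 1.4 CPM), Areg (20.5 ± 1.0 against 1.49 ± 0.22 CPM), Vegfa (441 ± 4.7 against 34.9 ± 0.30 CPM) and Trib3. Inflammatory genes rose as a group (12 higher, 0 lower of 21, median 0.80, camera adjusted p = 5.93e-18), as did YAP targets (11 higher, 2 lower of 15, 12 and 2 adjusted over the list alone, median 0.41, or 0.24 with library totals, camera adjusted p = 2.01e-12). Immediate early genes rose too (21 higher, 2 lower of 24, median 1.43, camera adjusted p = 2.66e-36). The phosphatase gene Dusp5 was at 226 ± 11 against 30.5 ± 1.8 CPM and Ccn2 at 1819 ± 93 against 194 ± 14 CPM. The hypoxia-inducible list gave 4 higher and 6 lower of 14 members, with a median of -0.07 (-0.03 with RLE factors, -0.23 with library totals and -0.01 after the GC and length correction) but a mean of 0.46 and a test upward (camera adjusted p = 1.82e-09).

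The glucose transporter gene Slc2a1 rose from 60.9 ± 5.6 to 128 ± 2.9 CPM at 3 h of glucose starvation, and Hk2, encoding hexokinase 2, from 43.4 ± 3.1 to 169.8 ± 5.6 CPM. The glycolysis list as a whole did not pass, as 7 of 23 rose and 6 fell (median 0.04, camera adjusted p = 0.108). In the list of glucose-responsive MondoA and ChREBP targets, which holds Txnip, 3 of 6 rose and 1 fell, with a median of 0.24, or 0.07 with library totals, a mean of -0.12 and camera adjusted p = 0.0259, adjusted p = 0.136 with estimated correlation. The falls were largest for Txnip and Castor2 (6.27 ± 1.3 against 33.4 ± 0.96 CPM), a relative of the arginine sensor Castor1, Ephb3 (3.88 ± 0.092 against 19.1 ± 1.2 CPM). The others were Dlg3 (5.48 ± 0.64 against 20.6 ± 0.33 CPM), Cdkn2d (6.66 ± 0.47 against 24.8 ± 0.054 CPM) and Zcchc24 (19.4 ± 0.061 against 66.9 ± 0.55 CPM). Mitotic genes fell, as 0 of 25 rose and 24 fell (median -0.65, camera adjusted p = 4.27e-17). Plk1 was at 61.4 ± 4.2 against 151 ± 9.1 CPM. In the autophagy list, 14 of 45 rose and 12 fell (15 and 12 adjusted over the list alone, median 0.07, camera adjusted p = 0.574). The list did not pass. Sqstm1 rose from 247 ± 12 to 569 ± 26 CPM, and Ulk1 fell from 49 ± 0.39 to 32 ± 3.4 CPM. Map1lc3b was at 113 ± 11 against 107 ± 0.58 CPM (edgeR adjusted p = 0.291, or 0.0286 without the first library of this group and 0.0104 after the GC and length correction). Lysosomal genes were mostly higher (32 higher, 2 lower of 47, 33 and 2 adjusted over the list alone, median 0.28, or 0.11 with library totals, camera adjusted p = 2.29e-05, adjusted p = 0.0631 with estimated correlation). So were the genes of ribosome biogenesis (25 higher, 0 lower of 30, median 0.36, or 0.19 with library totals, camera adjusted p = 1.75e-08). Transcripts of the mitochondrial genome were also higher (10 higher, 0 lower of 13, 12 and 0 adjusted over the list alone, median 0.41, or 0.25 with library totals, camera adjusted p = 0.00278, adjusted p = 0.46 with estimated correlation). The cholesterol list did not pass (5 higher, 7 lower of 25, median 0.03, camera adjusted p = 0.911). Of 7666 genes called, 3586 were higher and 4080 lower, and 1711 changed at least 2-fold (832 higher, 879 lower). RLE factors gave 51.5% higher instead of 46.8%, and 52.1% instead of 48.6% at 2-fold. Library totals alone gave 25.7% and 32.1%. They turned the medians of the called lists of NRF2 targets (9 higher, 2 lower of 22, median 0.11, camera adjusted p = 0.000123) and FOXO targets (6 higher, 3 lower of 16, median 0.09, camera adjusted p = 0.00617, adjusted p = 0.117 with estimated correlation) to -0.06 and -0.08.

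After 6 h of glucose starvation, ER chaperone, ATF4 and cholesterol genes were higher than in the control, while mitotic and interferon-stimulated genes were lower. Trib3 stood at 148 ± 0.95 against 6.88 ± 1.2 CPM, Ddit3, the gene of the stress factor CHOP, at 125 ± 0.81 against 14.2 ± 2.2 CPM and Hspa5 at 4139.6 ± 142 against 1419 ± 8.2 CPM. Of the ATF4 targets, 33 of 34 rose and 0 fell (median 1.87, camera adjusted p = 1.8e-135). Of the ER list, 22 of 24 rose and 0 fell (median 0.71, camera adjusted p = 5.68e-23). Herpud1 was at 357 ± 6.2 against 75.1 ± 1.8 CPM and Pdia4 at 591 ± 16 against 305 ± 3.3 CPM. In the cholesterol list, 23 of 25 rose and 0 fell (median 0.89, camera adjusted p = 3.02e-27). Hmgcs1 rose from 112 ± 4.2 to 245 ± 4.3 CPM and Insig1, a regulator of sterol synthesis, from 44.3 ± 1.7 to 142 ± 0.025 CPM. The largest increases were those of Angptl6 (11 ± 0.91 against 0.481 ± 0.15 CPM) and Trib3, Soat2 (2.05 ± 0.33 against 0.0983 ± 0.015 CPM). The others were Serpinb2 (4.99 ± 1.3 against 0.262 ± 0.12 CPM), Grem1 (293 ± 3.9 against 19.1 ± 2.4 CPM), a secreted antagonist of bone morphogenetic proteins, and Gadd45a (65.2 ± 1.2 against 5.81 ± 0.20 CPM). Ribosome biogenesis genes also rose (27 higher, 0 lower of 30, 28 and 0 adjusted over the list alone, median 0.55, camera adjusted p = 9.39e-18).

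Txnip remained low at 6 h of glucose starvation, at 0.606 ± 0.12 against 8.94 ± 0.93 CPM. The other largest falls were those of Egr1 (7.78 ± 0.27 against 82.3 ± 0.35 CPM) and Apol9a (3.58 ± 0.30 against 19.6 ± 1.4 CPM). The others were the RNA sensor Ifih1 (2.7 ± 0.17 against 14.6 ± 0.35 CPM), Cacna1h (14.3 ± 0.49 against 66.8 ± 7.9 CPM) and Scube3 (12.7 ± 0.49 against 52.7 ± 5.9 CPM). Interferon-stimulated genes fell (0 higher, 16 lower of 19, 0 and 18 adjusted over the list alone, median -0.95, camera adjusted p = 4.99e-06). Mitotic genes fell (0 higher, 24 lower of 25, 1 and 24 adjusted over the list alone, median -0.63, camera adjusted p = 1.26e-17). The proliferation marker Mki67 was at 232 ± 4.8 against 525 ± 28 CPM. DNA replication genes fell (1 higher, 20 lower of 26, median -0.24, or -0.37 with library totals, camera adjusted p = 0.000198). The autophagy list did not pass (18 higher, 10 lower of 45, 19 and 11 adjusted over the list alone, median 0.04, camera adjusted p = 0.267), with Ulk1 lower, at 29 ± 0.21 against 49 ± 0.39 CPM. Lysosomal genes were mostly higher (26 higher, 6 lower of 47, 28 and 6 adjusted over the list alone, median 0.29, or 0.16 with library totals, camera adjusted p = 0.000231, adjusted p = 0.119 with estimated correlation). Of 8414 genes that passed, 4124 were higher and 4290 lower. Of these, 1816 changed at least 2-fold (864 higher, 952 lower). By library totals alone 33.1% of the calls were higher instead of 49.0%, and 34.5% instead of 47.6% at 2-fold.

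After 12 h of glucose starvation, genes of the integrated and ER stress responses and autophagy genes were higher than in the control, and mitotic genes were lower. Ddit3 rose from 14.2 ± 2.2 to 326 ± 12 CPM (log2 fold change 4.52, SE 0.085, edgeR adjusted p = 1.14e-25). Trib3 rose from 6.88 ± 1.2 to 267 ± 11 CPM and Hspa5 from 1419 ± 8.2 to 4632 ± 25 CPM (log2 fold change 1.71, SE 0.053, edgeR adjusted p = 3.28e-21). Of the ATF4 targets, 34 of 34 rose and 0 fell (median 2.44, camera adjusted p = 2.43e-118). Of the ER list, 23 of 24 rose and 0 fell (23 and 1 adjusted over the list alone, median 1.26, camera adjusted p = 2.07e-37). Herpud1 was at 768 ± 8.4 against 75.1 ± 1.8 CPM. Synthetase genes (17 higher, 0 lower of 20, median 1.15, camera adjusted p = 5.15e-20) and one-carbon genes (10 higher, 1 lower of 11, median 1.40, camera adjusted p = 7.59e-24) rose. Aldh1l2 was at 949 ± 44 against 76.8 ± 0.69 CPM. The largest increases were those of Angptl6 (66.9 ± 3.1 against 0.481 ± 0.15 CPM), Trib3, Soat2 (3.28 ± 0.25 against 0.0983 ± 0.015 CPM), Ddit3, Ndrg1 (524 ± 14 against 23.2 ± 0.55 CPM) and Slc6a9 (369 ± 0.46 against 18.1 ± 0.44 CPM). In the autophagy list, 32 of 45 rose and 3 fell (median 0.34, camera adjusted p = 1.48e-06). Sqstm1 rose from 247 ± 12 to 848 ± 6.8 CPM, Atg14 from 12.7 ± 0.71 to 39.3 ± 0.67 CPM and Atg13 from 24.1 ± 1.2 to 67.3 ± 0.95 CPM. Ulk1 was at 50.0 ± 0.29 against 49 ± 0.39 CPM (edgeR adjusted p = 0.742, or 4.81e-06 with a log2 fold change of 0.35 after correction for GC content and length). Lysosome and TFEB targets rose, as 36 of 47 rose and 6 fell (37 and 6 adjusted over the list alone, median 0.59, camera adjusted p = 5.47e-10). Flcn was at 207 ± 3.8 against 51.1 ± 0.23 CPM and Mcoln1 at 112 ± 3.3 against 36.8 ± 1.4 CPM. Tfeb fell from 13.1 ± 0.81 to 7.24 ± 0.019 CPM.

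Ribosomal protein genes at 12 h of glucose starvation shifted by a small amount in the same direction, as 43 of 46 rose and 0 fell (44 and 0 adjusted over the list alone, median 0.44, camera adjusted p = 1.73e-07, adjusted p = 0.444 with estimated correlation). Rpl3 was at 2247 ± 51 against 1308 ± 52 CPM. Hypoxia-inducible genes rose (10 higher, 2 lower of 14, median 0.79, camera adjusted p = 2.8e-13), and the cholesterol list was higher (18 higher, 3 lower of 25, 18 and 4 adjusted over the list alone, median 0.51, camera adjusted p = 1.43e-05). Mitotic genes fell, as 0 of 25 rose and 25 fell (median -1.27, camera adjusted p = 1.11e-31). Plk1 was at 27.9 ± 1.7 against 151 ± 9.1 CPM. The largest falls were those of Egr1 (3.04 ± 0.54 against 82.3 ± 0.35 CPM) and Has2 (1.31 ± 0.14 against 15.4 ± 0.71 CPM), a hyaluronan synthase. Others were Gas1 (2.37 ± 0.14 against 27.2 ± 2.4 CPM), Pdgfb (2.13 ± 0.30 against 20.6 ± 0.47 CPM) and Olfml2b (2.36 ± 0.18 against 20.8 ± 0.65 CPM). Txnip was low, at 1.71 ± 0.21 against 8.94 ± 0.93 CPM. Inflammatory genes (4 higher, 13 lower of 21, median -1.49, camera adjusted p = 1.73e-07) and interferon-stimulated genes (0 higher, 15 lower of 19, 0 and 16 adjusted over the list alone, median -1.31, camera adjusted p = 4e-05) were mostly lower. So were YAP targets (0 higher, 12 lower of 15, median -0.66, camera adjusted p = 3.14e-08) and matrix genes (5 higher, 18 lower of 28, median -0.38, or -0.17 after GC and length correction, camera adjusted p = 2.35e-07, adjusted p = 0.0896 with estimated correlation). Immediate early genes were also mostly lower (5 higher, 14 lower of 24, median -0.68, camera adjusted p = 2.82e-05, adjusted p = 0.0846 with estimated correlation). Calls numbered 10340, with 5387 higher and 4953 lower. Among them, 3223 changed at least 2-fold (1427 higher, 1796 lower). With library totals alone 43.1% of the calls were higher instead of 52.1%, and 36.0% instead of 44.3% at 2-fold.

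**Figure D2:**
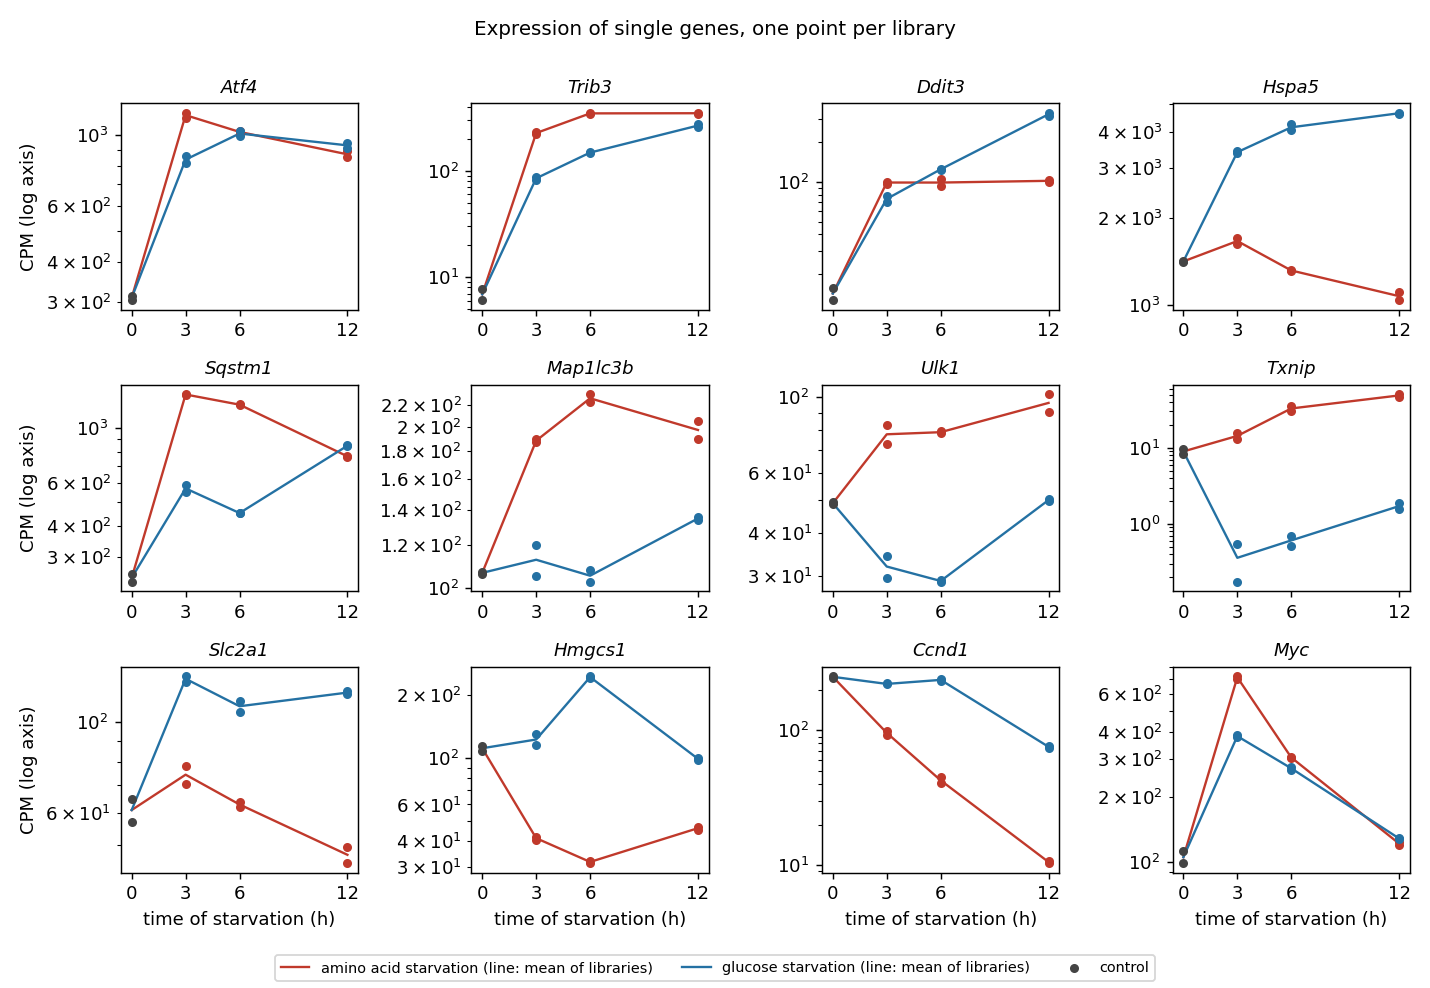
CPM (log axis) of 12 genes of the fixed panel against the time of starvation in hours, with 1 point per library and lines through the means of 2 libraries, for amino acid starvation (red), glucose starvation (blue) and the control (grey, 0 h). Trib3 rose in both starvations, Hspa5 reached 4632 CPM after 12 h without glucose and 1074 CPM without amino acids, and Txnip and Ccnd1 separated the starvations.

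Many genes went the same way in both starvations, which share the 2 control libraries and a handling not separable from starvation. At 3 h, 2358 genes were higher in both and 2517 lower in both, where independent lists would give 1000 and 1310. At 6 h these counts were 2223 and 2386 (1332 and 1428 if independent), and at 12 h 3096 and 2957 (1879 and 1587). Unchanged groups simulated against the same controls averaged 0 such genes (20 runs, edgeR), which cannot test the excess, as few genes are then called. Part of it may come from the shared controls. Fold changes of the starvations correlated across genes with r of 0.44, 0.389 and 0.506 at 3, 6 and 12 h. Simulated r was 0.473, 0.491 and 0.505 from shared controls alone, so r cannot test the excess either. Covariance of the fold changes was 0.479, 0.463 and 0.787, against 0.042, 0.043 and 0.042 simulated, a difference of 0.436, 0.42 and 0.745. In opposite directions went 961, 1936 and 1972 genes, all of which passed in the direct comparison, and 63, 138 and 118 changed at least 2-fold in both.

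At 3 h, amino acid starvation gave higher levels of immediate early and ATF4 target genes than glucose starvation, and lower levels of sterol and ER chaperone genes. Egr1 stood at 1352 ± 13 against 31.4 ± 0.28 CPM, Fos at 64.9 ± 5.2 against 4.46 ± 0.39 CPM and Junb at 703 ± 18 against 135 ± 9.2 CPM. Of the immediate early genes, 20 of 24 were higher and 1 lower (median 1.64, camera adjusted p = 1.09e-40). Among ATF4 targets, 33 of 34 were higher and 0 lower (median 0.86, camera adjusted p = 1.56e-34). Txnip differed the most of the panel (14.3 ± 1.7 against 0.358 ± 0.26 CPM, log2 fold change 5.32, SE 0.22, edgeR adjusted p = 1.53e-17). The other largest positive differences were those of Col11a2 (25.4 ± 0.81 against 1.82 ± 0.32 CPM), Cln3 (13.4 ± 0.87 against 1.34 ± 0.19 CPM) and Fosb (62.4 ± 0.95 against 7.38 ± 0.056 CPM). Slc38a2, a neutral amino acid carrier, was at 1817 ± 2.5 against 587 ± 33 CPM, and transporters were higher as a list (11 higher, 2 lower of 20, 12 and 2 adjusted over the list alone, median 0.65, camera adjusted p = 8.61e-10). The synthetase list was higher as well (13 higher, 4 lower of 20, median 0.22, camera adjusted p = 0.026, adjusted p = 0.351 with estimated correlation). FOXO targets were also higher (13 higher, 1 lower of 16, median 0.65, camera adjusted p = 8.61e-10), with the cyclin Ccng2 at log2 difference 2.71, SE 0.10.

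Autophagy genes were higher in amino acid than in glucose starvation at 3 h, as 23 of 45 were higher and 9 lower (median 0.18, camera adjusted p = 0.000255). Sqstm1 was at 1368 ± 2.2 against 569 ± 26 CPM, Gabarapl1 at 94.2 ± 0.46 against 35.8 ± 0.90 CPM and Ulk1 at 77.8 ± 6.9 against 32 ± 3.4 CPM (log2 fold change 1.28, SE 0.077, edgeR adjusted p = 2.66e-14). Lysosomal genes did not pass (10 higher, 25 lower of 47, 10 and 26 adjusted over the list alone, median -0.17, camera adjusted p = 0.182). DNA replication genes were higher (23 higher, 2 lower of 26, median 0.43, camera adjusted p = 9.19e-09). Cholesterol genes (0 higher, 22 lower of 25, median -0.73, camera adjusted p = 1.5e-18) and ER genes (3 higher, 21 lower of 24, median -0.77, camera adjusted p = 1.14e-12) were lower. Hspa5 was at 1669 ± 51 against 3394 ± 45 CPM. The most negative differences were those of Chst12 (1.43 ± 0.086 against 12.4 ± 0.35 CPM) and the long noncoding RNA Neat1 (210.5 ± 2.3 against 1751 ± 28 CPM). The others were Ampd3 (4.0 ± 0.45 against 25.2 ± 0.84 CPM), Sapcd2 (2.09 ± 0.14 against 12.7 ± 0.32 CPM), Zfp61 (1.77 ± 0.26 against 10.4 ± 2.1 CPM) and Tsku (7.41 ± 0.13 against 41.5 ± 1.8 CPM). Transcripts of the mitochondrial genome were lower (0 higher, 13 lower of 13, median -0.67, or -0.39 after GC and length correction, camera adjusted p = 4.46e-06, adjusted p = 0.327 with estimated correlation), beside their read shares of 4.0% and 6.54%. The test passed 9625 genes, 4720 higher and 4905 lower in amino acid starvation. Of these, 2462 changed at least 2-fold (1402 higher, 1060 lower).

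At 6 h, the starvations differed most, by list median, in cholesterol synthesis, where amino acid starvation had the lower level of all members: 0 of 25 were higher and 25 lower (median -2.30, camera adjusted p = 5.3e-65). Hmgcs1 was at 31.8 ± 0.69 against 245 ± 4.3 CPM (log2 fold change -2.94, SE 0.064, edgeR adjusted p = 1.02e-24). Fatty acid genes were lower too (0 higher, 12 lower of 13, median -0.94, camera adjusted p = 4.3e-13). Scd2 was at 123 ± 0.70 against 1166 ± 4.7 CPM. Of the ER list, 2 of 24 were higher and 22 lower (median -1.22, camera adjusted p = 2.31e-23). Pdia4 was at 87.4 ± 0.70 against 591 ± 16 CPM and Hspa5 at 1319 ± 9.3 against 4139.6 ± 142 CPM. Heat shock genes were lower (1 higher, 13 lower of 16, median -0.73, camera adjusted p = 4.96e-09). So were glycolysis genes (1 higher, 19 lower of 23, median -0.52, or -0.28 after GC and length correction, camera adjusted p = 0.000454, adjusted p = 0.159 with estimated correlation) and matrix genes (2 higher, 22 lower of 28, median -0.69, camera adjusted p = 1.48e-08, adjusted p = 0.0832 with estimated correlation). The most negative differences were those of Gask1b (2.51 ± 0.060 against 64.1 ± 5.0 CPM) and Cnn2 (27.1 ± 0.23 against 544 ± 12 CPM). Others were Cyp1b1 (3.1 ± 0.18 against 59.2 ± 1.9 CPM), Sorbs2 (1.55 ± 0.29 against 27.7 ± 1.5 CPM) and Ampd3 (1.71 ± 0.086 against 27.3 ± 1.0 CPM).

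Higher in amino acid starvation at 6 h were DNA replication (23 higher, 1 lower of 26, 24 and 1 adjusted over the list alone, median 0.86, camera adjusted p = 8.34e-15) and mitotic genes (22 higher, 1 lower of 25, median 0.69, camera adjusted p = 2.97e-11). Pcna, the sliding clamp of DNA polymerases, was at 674 ± 6.3 against 288 ± 7.9 CPM. The autophagy list was higher, as 27 of 45 were higher and 10 lower (28 and 10 adjusted over the list alone, median 0.28, camera adjusted p = 0.000229). Sqstm1 was at 1243 ± 12 against 452 ± 2.3 CPM, Map1lc3b at 226 ± 5.4 against 105 ± 3.8 CPM and Ulk1 at 78.9 ± 0.75 against 29 ± 0.21 CPM (log2 fold change 1.44, SE 0.077, edgeR adjusted p = 6.6e-16). ATF4 targets were again higher (29 higher, 1 lower of 34, median 0.78, camera adjusted p = 4.26e-16). Atf4 itself was at 1023 ± 12 against 1011 ± 24 CPM (edgeR adjusted p = 0.795, or 5.81e-06 with a log2 difference of 0.20 after correction for GC content and length). Egr1 (529 ± 5.2 against 7.78 ± 0.27 CPM) and Txnip (32.8 ± 3.0 against 0.606 ± 0.12 CPM) led the positive differences. The others were Col11a2 (54 ± 0.51 against 1.66 ± 0.10 CPM), Cln3 (38.8 ± 1.2 against 2.14 ± 0.51 CPM), Apobr (146 ± 1.4 against 10.8 ± 0.13 CPM) and Psd (117 ± 2.3 against 11.4 ± 0.27 CPM). Immediate early genes remained higher (15 higher, 6 lower of 24, median 0.82, camera adjusted p = 6.04e-11). Calls numbered 11294, with 5572 higher and 5722 lower. Among them, 4124 changed at least 2-fold (2165 higher, 1959 lower).

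At 12 h, amino acid starvation had lower levels of ER chaperone, sterol, heat shock and matrix genes than glucose starvation, and higher levels of mitotic and DNA replication genes. Of the ER list, 1 of 24 were higher and 23 lower (median -1.88, camera adjusted p = 4.97e-46). Hsp90b1 was at 673 ± 31 against 5029 ± 55 CPM, Calr at 1012 ± 17 against 4817 ± 66 CPM and Hspa5 at 1074 ± 47 against 4632 ± 25 CPM (log2 fold change -2.11, SE 0.054, edgeR adjusted p = 2.35e-23). Of the heat shock list, 1 of 16 were higher and 14 lower (median -1.30, camera adjusted p = 1.13e-17). Hspa8 was at 478 ± 3.5 against 6192 ± 4.2 CPM. Ribosomal protein genes were lower in every member, as 0 of 46 were higher and 46 lower (median -0.67, or -0.43 with library totals and -0.44 after GC and length correction, camera adjusted p = 5.34e-12, adjusted p = 0.315 with estimated correlation). Rpl6 was at 656 ± 5.7 against 1924 ± 62 CPM. Cholesterol genes (0 higher, 25 lower of 25, median -1.74, camera adjusted p = 5.3e-34) and glycolysis genes (1 higher, 20 lower of 23, 1 and 21 adjusted over the list alone, median -0.85, camera adjusted p = 3.65e-10) were lower too. So were ribosome biogenesis genes (4 higher, 22 lower of 30, 4 and 23 adjusted over the list alone, median -0.50, or -0.27 with library totals, camera adjusted p = 1.8e-05) and matrix genes (1 higher, 24 lower of 28, median -1.26, camera adjusted p = 6.14e-20). Slc2a1 was at 47.4 ± 3.1 against 118 ± 1.3 CPM and Aldoa at 246 ± 2.0 against 702 ± 29 CPM. The most negative differences were those of Gask1b (0.944 ± 0.16 against 37.2 ± 2.8 CPM) and Sorbs2 (0.298 ± 0.15 against 8.24 ± 0.84 CPM). The others were Ly6a (0.218 ± 0.095 against 5.92 ± 0.38 CPM), the intermediate filament gene Vim (99.3 ± 2.0 against 2214 ± 58 CPM), Cnn2 (15.2 ± 0.61 against 300.3 ± 15 CPM) and Tagln (9.82 ± 0.37 against 171 ± 4.8 CPM).

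Mitotic genes were higher in amino acid than in glucose starvation at 12 h, as 25 of 25 were higher and 0 lower (median 1.41, camera adjusted p = 4.96e-33). Top2a was at 1061 ± 13 against 287 ± 11 CPM and Aurka at 188 ± 0.23 against 30.1 ± 1.1 CPM. DNA replication genes were higher as well (22 higher, 1 lower of 26, 22 and 2 adjusted over the list alone, median 0.91, camera adjusted p = 1.85e-11). Rrm2 was at 526 ± 19.9 against 208 ± 2.0 CPM. The autophagy (20 higher, 14 lower of 45, median 0.08, camera adjusted p = 0.153), lysosome (18 higher, 23 lower of 47, 19 and 23 adjusted over the list alone, median -0.11, camera adjusted p = 0.583) and ATF4 lists (9 higher, 14 lower of 34, median -0.08, camera adjusted p = 0.486) did not pass. Within them Ulk1 (96.1 ± 8.0 against 50.0 ± 0.29 CPM) and Map1lc3b (197 ± 11 against 135 ± 1.1 CPM) were higher. Bnip3, a receptor for mitochondrial autophagy, was lower (16.3 ± 0.32 against 49.9 ± 1.6 CPM), and Ddit3 was lower (102 ± 2.8 against 326 ± 12 CPM). Txnip (48.7 ± 2.3 against 1.71 ± 0.21 CPM), Egr1 (45.4 ± 3.3 against 3.04 ± 0.54 CPM), Col11a2 (33.1 ± 1.7 against 1.34 ± 0.13 CPM), Apobr (213 ± 5.4 against 18.9 ± 1.3 CPM) and Mast1 (22.6 ± 1.4 against 2.46 ± 0.24 CPM) were among the largest positive differences. Serpinb2 was at 4.03 ± 0.093 against 0.0557 ± 0.079 CPM, with no read in 1 of the 2 glucose-starved libraries. NRF2 targets were lower (1 higher, 17 lower of 22, median -0.81, camera adjusted p = 3.99e-06). Of 11343 genes called, 5758 were higher and 5585 lower, and 4164 differed at least 2-fold (2161 higher, 2003 lower). With library totals alone 65.5% were higher instead of 50.8%, and 69.3% instead of 51.9% at 2-fold.

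**Figure D3:**
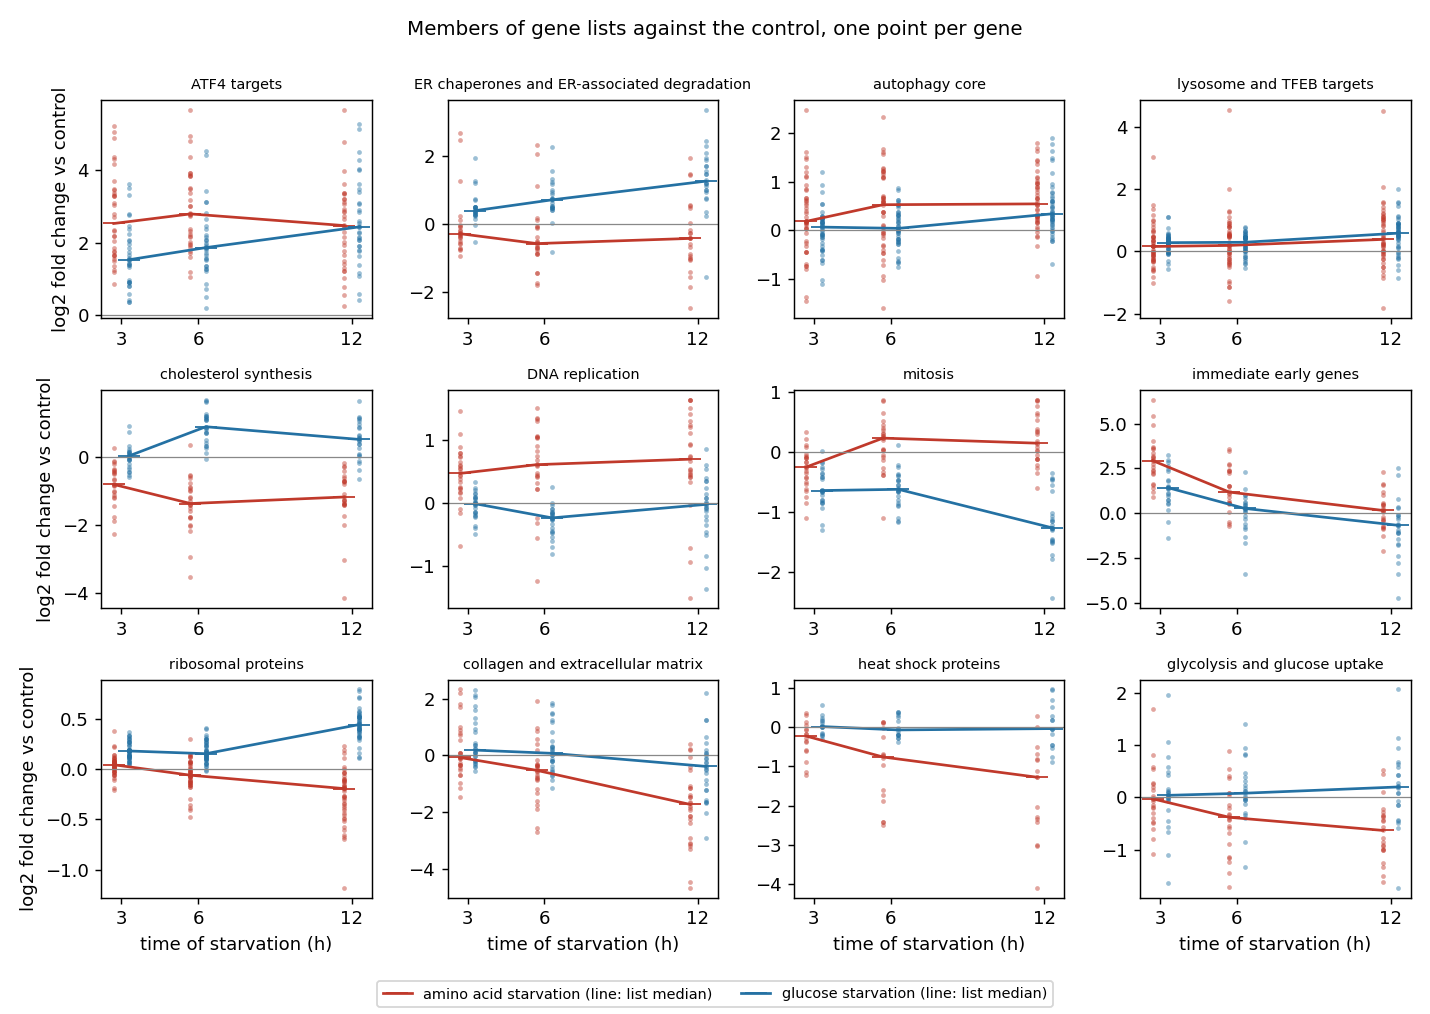
Log2 fold change against the control of the measured members of 12 gene lists, with 1 point per gene and lines through the list medians at 3, 6 and 12 h of amino acid (red) and glucose (blue) starvation. The ER list had medians of -0.42 and 1.26 at 12 h, the cholesterol list -1.37 and 0.89 at 6 h, and the mitosis list 0.14 and -1.27 at 12 h, in amino acid and glucose starvation.

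**Figure D4:**
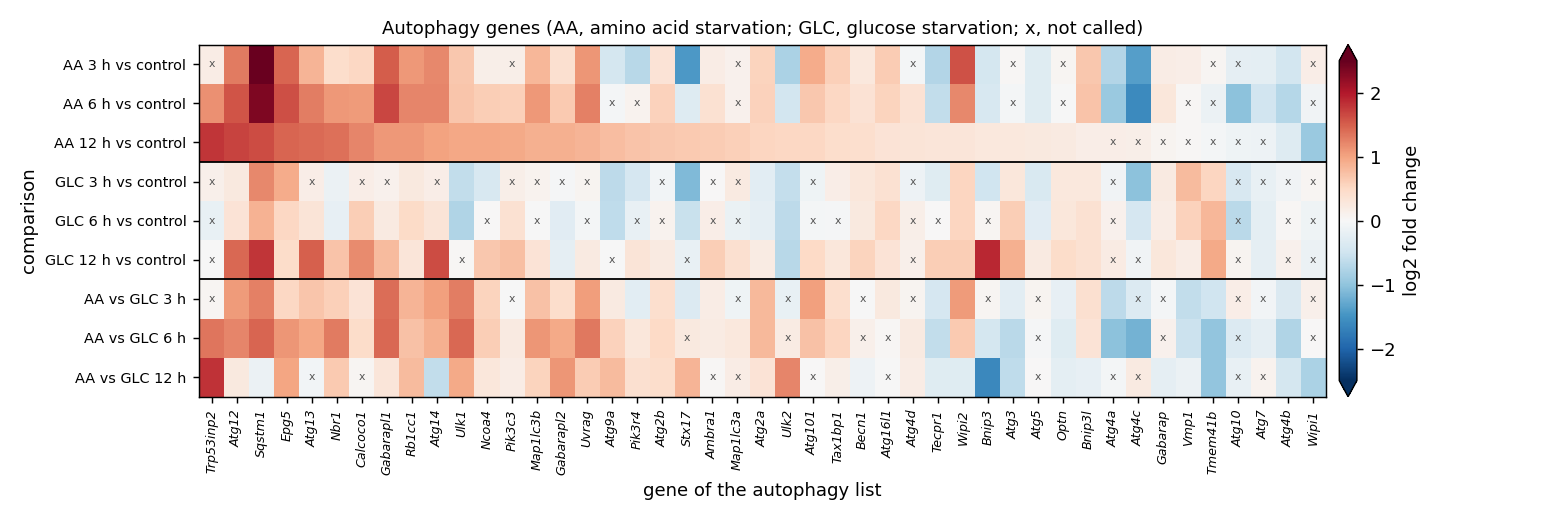
Log2 fold changes of the 45 genes of the autophagy list (columns) in 9 comparisons (lines of the map), from blue (lower) to red (higher), with x marking genes that edgeR did not call. Against the control, 36 genes rose after 12 h of amino acid starvation and 32 after 12 h of glucose starvation, and at 3 h 25 and 14 did.

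Between 3 and 12 h of amino acid starvation, the early genes subsided and matrix, YAP and inflammatory genes fell. Of the immediate early genes, 0 of 24 rose and 24 fell (median -2.83, camera adjusted p = 9.5e-45). Of the inflammatory genes, 0 of 21 rose and 19 fell (median -2.69, camera adjusted p = 3.38e-25). Cxcl1 fell from 77.4 ± 0.072 to 0.87 ± 0.32 CPM, Has2 from 131 ± 0.48 to 1.84 ± 0.15 CPM and Ly6a from 13.8 ± 2.0 to 0.218 ± 0.095 CPM. Matrix genes (0 higher, 27 lower of 28, median -1.61, camera adjusted p = 5.77e-33) and YAP targets (0 higher, 14 lower of 15, median -1.80, camera adjusted p = 7e-21) fell. So did heat shock genes (1 higher, 15 lower of 16, median -1.0, camera adjusted p = 2.12e-09). Angptl6 (31.1 ± 1.2 against 1.65 ± 0.34 CPM), the phosphatase Ppm1e (36.9 ± 0.39 against 3.54 ± 0.10 CPM) and Napb (21.4 ± 0.14 against 2.16 ± 0.12 CPM) rose the most. ATF4 targets as a list did not pass (8 higher, 18 lower of 34, median -0.21, camera adjusted p = 0.278). Ddit4 fell from 189 ± 3.7 to 44 ± 5.1 CPM. Autophagy genes were more often higher (24 higher, 10 lower of 45, 24 and 11 adjusted over the list alone, median 0.23, or 0.54 with library totals, camera adjusted p = 0.0364, adjusted p = 0.081 with estimated correlation), with Sqstm1 lower (768 ± 8.0 against 1368 ± 2.2 CPM, log2 fold change -0.83, or -0.52 with library totals). The test passed 12099 genes, 6284 higher and 5815 lower at 12 h. Of these, 5348 changed at least 2-fold (2758 higher, 2590 lower). Library totals alone gave 68.0% higher instead of 51.9%, and 69.0% instead of 51.6% at 2-fold. They turned the medians of the ER (4 higher, 17 lower of 24, median -0.26, camera adjusted p = 0.0364, adjusted p = 0.354 with estimated correlation) and ribosomal protein lists (1 higher, 37 lower of 46, median -0.30, or -0.18 after GC and length correction, camera adjusted p = 0.0436, adjusted p = 0.748 with estimated correlation) to 0.05 and 0.01.

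Between 3 and 12 h of glucose starvation, ATF4, ER and autophagy genes rose, while immediate early, inflammatory and mitotic genes fell. Among ATF4 targets, 26 of 34 rose and 1 fell (27 and 2 adjusted over the list alone, median 0.85, camera adjusted p = 6.71e-21). Of the ER list, 22 of 24 rose and 1 fell (median 0.89, camera adjusted p = 3.36e-17). Ddit3 rose from 74.3 ± 5.9 to 326 ± 12 CPM. In the autophagy list, 30 of 45 rose and 3 fell (median 0.40, camera adjusted p = 2.12e-05). The largest increases were those of Angptl6 (66.9 ± 3.1 against 2.08 ± 0.17 CPM), the mitochondrial carrier Slc25a42 (24.2 ± 0.59 against 3.61 ± 0.98 CPM) and Pdk1 (42.1 ± 2.0 against 6.35 ± 0.43 CPM), a kinase that restrains pyruvate oxidation. Has2 fell from 94.9 ± 8.9 to 1.31 ± 0.14 CPM and Sema7a from 51.2 ± 2.2 to 1.96 ± 0.11 CPM, and Serpinb2 was at 0.0557 ± 0.079 against 13.3 ± 0.66 CPM. Immediate early (2 higher, 22 lower of 24, median -2.36, camera adjusted p = 5.78e-40), inflammatory (0 higher, 16 lower of 21, median -2.19, camera adjusted p = 4.44e-31) and mitotic genes (1 higher, 23 lower of 25, median -0.57, camera adjusted p = 1.77e-08) were lower at 12 h. The test passed 10143 genes, 5631 higher and 4512 lower. Among them, 3202 changed at least 2-fold (1503 higher, 1699 lower).

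The change from 3 to 12 h differed between the starvations in ATF4, ER, heat shock, cholesterol and mitotic genes, among other lists. In the test of that difference, taken as amino acid minus glucose starvation, ATF4 targets (0 higher, 33 lower of 34, median -1.01, camera adjusted p = 1.69e-27) and ER genes (0 higher, 21 lower of 24, median -1.09, camera adjusted p = 5.52e-28) were on the lower side. Heat shock genes (0 higher, 14 lower of 16, median -0.81, camera adjusted p = 3.54e-15) and cholesterol genes (2 higher, 20 lower of 25, median -0.89, camera adjusted p = 1.35e-11) were lower too. Mitotic genes were on the higher side (23 higher, 0 lower of 25, 24 and 0 adjusted over the list alone, median 1.15, camera adjusted p = 7.81e-28). Ddit3 (log2 fold change -2.09, SE 0.10, edgeR adjusted p = 1.02e-15) and Ddit4 (log2 fold change -2.79, SE 0.10, edgeR adjusted p = 5.91e-19) were lower. Vim, Sorbs2 and Cxcl1 had the most negative differences, at -4.35, SE 0.082, -4.40, SE 0.29 and -4.29, SE 0.22, and Gas1 and H1f10 were among the most positive, at 3.12, SE 0.20 and 2.91, SE 0.18. The autophagy list did not pass (9 higher, 18 lower of 45, 10 and 21 adjusted over the list alone, median -0.15, camera adjusted p = 0.261). Its member Sqstm1 was lower (log2 fold change -1.41, SE 0.074, edgeR adjusted p = 2.07e-15). Of 8397 genes called, 3845 were higher and 4552 lower. Of these, 2858 changed at least 2-fold (1361 higher, 1497 lower). Library totals alone gave 66.1% higher instead of 45.8%, and 69.2% instead of 47.6% at 2-fold.

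The panel genes Fgf21, Gdf15 and Arrdc4 had low counts. Fgf21, a secreted factor, rose from 0.0874 CPM in the control to 3.39, 1.83 and 0.691 along amino acid starvation (log2 fold changes of 5.23, SE 0.42, 4.35, SE 0.43 and 2.94, SE 0.48) and 0.325, 0.403 and 1.76 along glucose starvation (1.86, SE 0.57, 2.16, SE 0.54 and 4.28, SE 0.44). Its call at 3 h of glucose starvation was lost without the first library of that group (edgeR adjusted p = 0.0643) and with only the groups compared (0.0553). Its changes over time differed (log2 fold change -4.72, SE 0.47, edgeR adjusted p = 1.7e-09). Gdf15, a stress cytokine, rose at 3 and 6 h of amino acid starvation (log2 fold changes of 3.10, SE 0.52 and 2.03, SE 0.54). Group means of Gdf15 and Arrdc4 reached at most 1.43 and 1.94 CPM. Without the second control library, the calls of Gdf15 at 12 h of amino acid and glucose starvation and of Arrdc4 at 12 h of amino acid starvation were lost (edgeR adjusted p = 0.0526, 0.0685 and 0.0636). Without the first starved library, those of Gdf15 in glucose and of Arrdc4 in amino acid starvation were lost too (0.108 and 0.0988).

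Markers of other cell types were fixed before the data were examined. Of the lists of macrophage (3 genes measured), endothelial (7), skeletal muscle (5) and adipocyte markers (4), none passed camera in any of the 12 comparisons, with smallest adjusted p of 0.362, 0.169, 0.209 and 0.603. The epithelial and erythroid lists had 1 measured member each and were not tested. Neural markers fell after 12 h of amino acid starvation (0 higher, 3 lower of 5, median -1.14, camera adjusted p = 0.00608). The members that passed were Tubb3, Nes and Stmn2 (log2 fold changes of -2.63, SE 0.10, -1.14, SE 0.055 and -2.19, SE 0.11), which encode cytoskeletal proteins or their regulators. The neural list was also lower in amino acid than in glucose starvation at 6 h (1 higher, 4 lower of 5, median -0.79, camera adjusted p = 0.0231, adjusted p = 0.0832 with estimated correlation). It was lower at 12 than at 3 h of amino acid starvation (2 higher, 3 lower of 5, median -1.52, camera adjusted p = 0.0319, adjusted p = 0.112 with estimated correlation) and of glucose starvation (2 higher, 3 lower of 5, median -0.38, camera adjusted p = 0.0352, adjusted p = 0.108 with estimated correlation).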

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

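Of the tests in this part, those of the general fall of abundant genes, of overlapping genes and of transcription past gene ends were fixed before their result was seen, and those of handling, GC content and scaling were chosen after. The tests of overlapping genes and of transcription past gene ends at 3 and 6 h of amino acid starvation were also chosen after.

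These results were singled out because the starvations differed in a direct test, by edgeR for genes and by camera for lists. Amino acid and glucose starvation differed in 9625 genes at 3 h, 11294 at 6 h and 11343 at 12 h, and in the change from 3 to 12 h of 8397 genes. Calls in opposite directions against the control numbered 961, 1936 and 1972 at 3, 6 and 12 h, at each time fewer than independent lists would give. As median log2 difference, amino acid minus glucose starvation, with calls against the control in opposite directions, the ER list differed by -1.22 at 6 h and -1.88 at 12 h, the cholesterol list by -2.30 and -1.74, the DNA replication list by 0.86 at 6 h and the ribosomal protein list by -0.67 at 12 h. With an estimated correlation, the ER calls against the control in amino acid starvation were lost (adjusted p = 0.199 at 6 h and 0.19 at 12 h). So were those of the ribosomal protein list at 12 h (0.816 in amino acid and 0.444 in glucose starvation against the control, and 0.315 between them). Its median in amino acid starvation was -0.19, or -0.06 with library totals and -0.04 after correction for GC content and length, and its difference between the starvations was then -0.43 and -0.44. Among panel genes in opposite directions, the log2 differences were 5.32, 5.74 and 4.85 for Txnip at 3, 6 and 12 h. They were 1.28 and 1.44 for Ulk1 at 3 and 6 h, -2.94 for Hmgcs1 at 6 h, and -2.11 for Hspa5, -1.32 for Slc2a1 and -0.65 for Hk2 at 12 h. The fall of Hk2 against the control in amino acid starvation, a log2 fold change of -0.22, did not pass edgeR with library totals (-0.08, adjusted p = 0.273), without the first control library (-0.14, 0.104) or without the second starved library (-0.17, 0.0577). It was -0.12 after correction for GC content and length (adjusted p = 0.0392) and -0.36 without the first starved library (0.000206). Between the starvations Hk2 was at -0.42 with library totals.

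Immediate early genes were higher at 3 h of both starvations, when all starved cells had changed medium. Handling as the cause of the larger rise in amino acid starvation is argued against, since both had the same handling and the list's median log2 difference was 1.64 (95% interval over 24 members 0.46 to 2.30). For the part common to both starvations, the median of 1.43 after 3 h without glucose (0.94 to 1.78, and -0.68 at 12 h), starvation and the change of medium cannot be told apart, because no group had new medium without starvation.

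Matrix genes were lower at 12 h of amino acid starvation. The matrix list's median against the control, -1.72 over 28 genes, was -1.62 after GC and length correction (95% interval -2.24 to -1.21). This argues against that bias as the whole cause. Library totals only shift every gene by 0.13, the median to -1.59 (-2.05 to -1.13), and so test no other scaling. The -1.72 lay at percentile 0 of 10000 random lists matched on mean expression, whose medians ran from -0.47 to 0.20 (95%). This argues against a general fall of abundant genes. A response to amino acid loss stays a hypothesis.

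In amino acid starvation, low genes tended to follow the abundant gene upstream of them. Among 157 pairs within 5 kb and without annotated overlap, fold changes at 12 h correlated across genes with rho of 0.24, or 0.29 above 100 pairs over 100 kb apart (95% interval 0.05 to 0.53), too wide to settle whether overlapping reads could be the source there. At 3 and 6 h that difference was 0.36 (0.12 to 0.61) and 0.42 (0.16 to 0.67), beyond the bound of 0.1 set for 12 h, which argues against reads of annotated overlapping genes as the source at these times (of the other comparisons, 12 against 3 h also passed it, at 0.11 to 0.59), but in 6 of the 12 comparisons the interval included 0, among them 3, 6 and 12 h of glucose starvation against the control (-0.07 to 0.43, -0.10 to 0.40 and -0.13 to 0.35). Transcription past the end of the upstream gene may contribute, as the correlation exceeded that of 65 pairs with the low gene upstream by 0.35 at 3 h of amino acid starvation (0.06 to 0.64), but the differences of 0.29 at 6 h (-0.007 to 0.57) and 0.24 at 12 h (-0.04 to 0.53) leave this open. That interval also lay above 0 at 12 h of glucose starvation (0.06 to 0.63) and for 12 against 3 h of amino acid starvation (0.04 to 0.61), and in none of the other 7 comparisons.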

How the results depend on the processing

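The settings for overlapping genes, GC content and length, and the longest transcript were chosen after seeing the data, and all others before. Of 419 counts under alternatives, 387 lay within 1.5 times the main count. Another 30 moved when genes overlapping another were left out, because only 10438 of 17696 genes were then tested: against the control 6239, 6814 and 6901 genes passed after 3, 6 and 12 h of amino acid starvation (2109, 2792 and 2962 by at least 2-fold) and 4470, 4975 and 6055 of glucose starvation (1055, 1151 and 1959). Between starvations 5734, 6688 and 6668 passed (1575, 2578 and 2600), between 12 and 3 h 7088 for amino acid (3290) and 6048 for glucose starvation (1998), and for the difference of these changes 4977 (1779). Shared calls were then 2852, 2693 and 3506 in the same direction and 560, 1206 and 1170 in opposite directions. The remaining 2 were the 224 list calls by camera, 145 with an estimated correlation and 337 with fry, which tests another question.

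Library totals instead of TMM moved the median log2 fold change of all genes by -0.18, 0.13, -0.17, -0.13 and -0.10 (3 and 12 h of amino acid, 3, 6 and 12 h of glucose starvation against the control), 0.24 (between starvations at 12 h), 0.31 (12 against 3 h of amino acid starvation) and 0.25 (difference of changes), so that small changes hold only relative to these shifts. They also turned the majority of the calls at 6 h between starvations (52.8% higher instead of 49.3%) and of those of at least 2-fold between 12 and 3 h of glucose starvation (52.4% instead of 46.9%). With RLE factors all shifts were at most 0.06 in size, but majorities turned too. Of 669 gene and comparison pairs, 6 results reversed, all of them amino acid against glucose starvation at 12 h with small main values. By library totals Atf4 was at 0.15 (edgeR adjusted p = 0.0129), Sqstm1 at 0.10 and Myc at 0.16. After correction for GC content and length Atf4 was at 0.11, Chac1 at 0.11 and Sqstm1 at 0.028. The cause was not tested. Calls were lost in 12 pairs with library totals, 5 with only the groups compared, 4 each with the GC and length correction and with no filter, 2 each with DESeq2 and RLE factors, 1 with the longest transcript, 0 with the stricter filter or without overlapping genes, and 42 combinations of pair and library when 1 library was left out. In that fit the lone library is assumed to vary like the other groups. These 42 concern Tfeb, Hk2, Gdf15, Arrdc4, Fgf21, Myc, Gabarapl1, Hmgcs1, Ccnd1, Ulk1, Sqstm1 and Atf4, in comparisons for which no call is named in the text, except Hk2 at 12 h of amino acid starvation (above) and those given for Fgf21, Gdf15 and Arrdc4. Without 1 library, calls ranged from 6555 to 6837 at 3 h of glucose starvation and from 10705 to 10952 at 12 h of amino acid starvation against the control.

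Replicate numbers did not pair the samples: differences between replicates 1 and 2 correlated with r of -0.035 to 0.054 over 21 pairs of groups (median 0.015, across genes). With the replicate block, calls at 12 h of amino acid starvation against the control went from 11841 to 11952, of which 11789 were shared, and no pair of gene and comparison lost its call. DESeq2 called 11472 there, 11381 of them shared. Low counts limit Serpinb2 in glucose starvation at 12 h, Soat2 and Serpinb2 in the control, and Txnip in glucose starvation.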

Other observations

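The test of serum response factor targets was fixed before its result was seen, although after the falls of Cnn2, Tagln, Vim and Actg1 were known, and those genes were left out of it.

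Beyond the fixed lists, genes of actin filaments and focal adhesions fell at 12 h of amino acid starvation. Of 29 measured cytoskeletal genes known as targets of serum response factor, a transcription factor controlled by actin and serum, 25 were lower and 1 higher than in the control, with a median log2 fold change of -1.62. Acta2, encoding smooth muscle actin, had a log2 fold change of -1.84 (edgeR adjusted p = 7.37e-19), Tpm1, a tropomyosin, -2.92 (1.76e-26), Tgfb1i1 -3.02 (6.67e-24) and Flna, filamin A, -1.71 (1.07e-19). At 3 h the list went the other way, with 20 genes higher and 4 lower after amino acid starvation (median 0.44) and 23 higher and 1 lower after glucose starvation (median 0.61). At 12 h of glucose starvation 15 were lower and 4 higher (median -0.13). From 3 to 12 h the list fell in both starvations, with 27 genes lower and 0 higher by edgeR without amino acids (median -2.05), and 26 lower and 1 higher without glucose (median -0.80). The genes named here were chosen after their values were seen.

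A larger loss of serum response factor output at cytoskeletal genes in prolonged amino acid starvation is a hypothesis for this pattern. In the direct comparison with glucose starvation at 12 h, which shares the handling, 23 of the 29 genes were lower and 1 was higher, and the median of -1.18 lay at percentile 0 of 10000 random lists matched on mean expression (95% of random medians from -0.55 to 0.17). The exception was Mylk, at levels of few reads (at most 0.854 CPM). The falls are what the hypothesis needs, but could also follow from other losses of actin and adhesion genes, including that of YAP targets. Immediate early genes, which also respond to serum, went the other way in that comparison (median 0.66). The factor's activity was not measured.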
